A study of Mus musculus with 4 samples.

How the data were processed

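Transcripts of mouse hematopoietic stem cells were measured on 4 single-colour Agilent microarrays that lay on 1 slide and were read in 1 scan. The fresh cells were lysed 7 days before the cultured ones, and batches of RNA extraction or labelling are not given and could not be told apart from the groups. Per the labels, bone marrow of 10 male C57BL/6J mice was pooled and cells with the surface phenotype CD150+ CD41- CD48- CD34- Flt3- LSK (lineage-negative, Sca-1-positive, Kit-positive, the gate for long-term repopulating stem cells) were sorted. They were lysed at once (fresh, 1 array) or cultured for 7 days in SF-O3 medium with 3 ng/mL stem cell factor, 0.1 ng/mL thrombopoietin and 4% bovine serum albumin (BSA), either nBSA (1 array) or reconstituted BSA (2 arrays). Stem cell factor and thrombopoietin are the ligands of the receptors Kit and Mpl. The labels do not define nBSA, and the name of the file deposited for that sample can be read as fatty acid added to BSA, so what separates the albumin preparations is unsure. The labels also do not say how the albumin was reconstituted and do not say whether the 2 reconstituted BSA arrays came from separate cultures. They also differ on whether cultured cells were sorted again before lysis or only centrifuged.

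The deposited scanner files hold the processed spot intensity of each feature, background-subtracted and detrended by Agilent Feature Extraction version 11.5.1.1 per the file headers, with no scaling between arrays. The processing notes of the authors name version 9.5.3 instead. Low intensities had been replaced by a surrogate value, so a difference against a gene at that floor is bounded by the background. The value table deposited by the authors holds log2 intensities less each array's 75th percentile, a scale found from the values because the labels leave the method of normalization unstated. The scanner files put on that scale gave the same values as the table (Pearson's r of 1 over probes on each array).

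Each array had 62976 spots, of which 59305 were not controls and stood for 55681 probes. Outlier spots, between 123 and 164 per array, were dropped, spots of 1 probe were averaged, and the 75th percentile of the non-control probes was subtracted from the log2 processed intensity. Probes were named from their RefSeq accession where it matched the supplied gene table of mouse assembly GRCm38.p6 (28026 probes) and otherwise from the symbol in the files (5734 probes), and 21921 probes had no gene name. Genome positions are those of the probes in the files, on build mm9. An annotation of that build was not used here, so exon, intron or untranslated region is not given.

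A probe was kept where Feature Extraction marked it as well above background on every array of at least 1 group, and the probe with the highest mean level stood for a gene with several, which left 16719 genes. Spots well above background made up 52.6% of the fresh array, 60.5% of the nBSA array and 56.3% and 59.5% of the reconstituted BSA arrays, and no spot was saturated. Precision was limited by the number of arrays. The pair of reconstituted BSA arrays differed by 2-fold or more in 39.4% of genes in the dimmest of 10 bins of level and in 2.39% in the brightest. Where the dimmer group had no array well above background, a fold is given as "at least". It was computed against the lowest level that was well above background on the dimmer arrays, or the gene's own level where that was higher. For reconstituted BSA the mean of both arrays was used. A probe not well above background can lie above that lowest level, so these bounds are nominal and not strict. Where the probe that stood for a gene was at background but another probe of the gene was not, the bound is that of the first probe. Where only 1 of both reconstituted BSA arrays was well above background, the difference is given as fitted and depends on the surrogate value. Among 4544 genes with several probes, other probes of the gene lay 2-fold apart in opposite directions in 403 genes for reconstituted BSA against fresh, 214 for reconstituted BSA against nBSA and 464 for nBSA against fresh, and for a gene whose difference is printed, another probe is given where its difference lay more than 1 away on the log2 scale.

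The comparisons were reconstituted BSA against fresh, nBSA against fresh, and reconstituted BSA against nBSA. For those with the replicated group, limma version 3.58.1 (R version 4.3.3, data.table version 1.17.8) fitted 3 group means with eBayes, and Benjamini-Hochberg adjustment over all genes took an adjusted p under 0.05 as the threshold. The spread came from the reconstituted BSA pair alone, with 1 residual degree of freedom and a prior of 2.12, and the lone arrays were assumed to vary like that pair. Beside it stands a size rule, at least 2-fold the same way on both reconstituted BSA arrays. All 2-fold counts use fitted values, also for genes at background, so a counted gene may have a bound under 2-fold. No p was computed for nBSA against fresh, where genes at least 2-fold apart were counted. Tables were made with Python version 3.11.15, numpy version 2.4.6 and pandas version 2.3.3.

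The 33 gene lists were fixed before the data were examined: HSC identity, quiescence, DNA replication and S phase, G2/M and mitosis, MYC and ribosome biogenesis, glycolysis, TCA cycle and respiratory chain, fatty acid oxidation, PPAR targets and lipid storage, fatty acid synthesis and desaturation, cholesterol synthesis and uptake, LXR targets and cholesterol efflux, hypoxia response, ER stress and amino acid response, p53 targets, antioxidant and NRF2 targets, immediate early genes, heat shock proteins, interferon response, NF-kB and inflammatory response, cytokine and STAT5 targets, autophagy and lysosome, adhesion and niche interaction, megakaryocyte and platelet markers, erythroid markers, neutrophil and granulocyte progenitor markers, monocyte, macrophage and dendritic cell markers, mast cell, basophil and eosinophil markers, B cell markers, T and NK cell markers, stromal and endothelial markers, multipotent and lymphoid progenitor markers, and sort markers and cytokine receptors. A list stood apart where the median log2 difference of its measured members lay below the 2.5th or above the 97.5th percentile of 10000 random lists of the same size matched on level in 20 bins. The percentile describes these arrays and is not a test across replicates. By chance 1.65 of 33 lists of independently drawn genes would stand apart. Members of a list may vary together and some lists share genes, so the number between arrays of 1 condition can be higher. Between both reconstituted BSA arrays 3 of 33 lists stood apart.

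Genes were named by a rule set in advance. For each comparison with reconstituted BSA these were the 10 highest and the 10 lowest that passed limma and the size rule, filled, since limma called none, by the size of the smaller of both arrays' differences. For nBSA against fresh they were the 10 highest and the 10 lowest by log2 difference among genes well above background on at least 1 of the arrays. Clone and predicted gene names were passed over. From each list up to 4 members with the largest difference in a comparison were eligible, and all of the sort markers. Genes outside this rule are said to have been chosen after their values were seen.

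The procedure was tested on simulated data with the spread of the reconstituted BSA pair for the comparison with fresh cells, over 16719 genes. Of 50 genes each changed by 4-, 16-, 64- and 1024-fold, limma called 0 at each size with an adjusted p under the threshold. Few genes were changed here, and only against fresh cells, while the adjusted p depends on the share of genes that differ. The power of limma in these data is therefore not known, and a count of 0 is not read as a lack of differences. The size rule took 64%, 98%, 98% and 100% of them and 13.1% of unchanged genes. Simulated lists of 20 genes stood apart in 6.5% of cases with no shift and in 100% with a log2 shift of 1.

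Alternatives were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over probes well above background on all arrays, the authors' value table, no filter on dim probes, only genes well above background on all arrays, the mean over the probes of a gene, removal of saturated genes, eBayes with trend and robust, a 4-fold threshold, limma for nBSA against fresh, the mean of a list in place of its median, and each reconstituted BSA array left out.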

Results

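The data are 4 microarray profiles of purified mouse hematopoietic stem cells (HSCs): 1 of freshly sorted cells, 1 of cells cultured for 7 days with 4% nBSA and 2 of cells cultured for 7 days with 4% reconstituted BSA. Levels are log2 processed intensities with each array's 75th percentile at 0, and differences are between such levels. For 16719 genes the signal was well above background in at least 1 group. Values after ± are limma's standard errors for 2 reconstituted BSA arrays against 1 array. They blend a gene's spread within that pair with the spread of the pair over all genes. Genes on which both arrays nearly coincide therefore share a value of 0.44. The fresh and nBSA groups had no replicate.

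Culture in reconstituted BSA was set against fresh cells to see how the transcripts of stem cells differed after 7 days outside the animal. The series title names maintenance of quiescent HSCs as the aim of the work. After culture, most immediate early genes were far lower than in fresh cells, and most megakaryocyte and platelet genes and genes of cholesterol synthesis were higher. The median of the interferon response list was also lower, and those of the hypoxia response and mitosis lists were higher. By fitted values, only 9 of 19 hypoxia and 9 of 27 mitosis members were at least 2-fold higher on both arrays. Of the 33 lists, 8 stood apart as higher and 5 as lower.

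Immediate early genes, whose transcription follows a stimulus within minutes, had a median log2 difference of -4.93 over 20 measured members, below all random lists, and 18 of 20 were at least 2-fold lower on both reconstituted BSA arrays. Fosb, a subunit of the AP-1 transcription factor, had a level of 8.65 on the fresh array and of -1.43 on each reconstituted BSA array, a difference of -10.09 ± 0.44. Fos, another member of that family, was at 6.82 in fresh cells and not well above background after culture, which made it at least 1657-fold lower. Its probe lies on chromosome 12 from 86817900 to 86817959 (mm9), and that of Fosb on chromosome 7 from 19888168 to 19888227 (mm9). Atf3, a stress-induced transcription factor, was at least 77.6-fold lower and Ier2 at least 54.0-fold lower. limma called 12 of the 20 genes adjusted over the list alone (smallest adjusted p = 0.00137) and 0 adjusted over all genes. The list also differed between both reconstituted BSA arrays, by a median of -0.53 over genes. Its median difference from fresh cells was -5.64 on the first array and -3.98 on the second.

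Megakaryocyte and platelet markers had a median log2 difference of 3.80, above all random lists, with 14 of 18 members at least 2-fold higher on both arrays and 0 lower. Ppbp, a chemokine of platelet granules, was not well above background in fresh cells and had levels of 5.10 and 4.51 after culture, at least 313-fold higher. Its probe lies on chromosome 5 from 91198970 to 91199029 (mm9). The thrombin-activated receptor F2rl2 was higher by 6.13 ± 0.53 and Gp1ba, a subunit of the platelet receptor for von Willebrand factor, by 6.08 ± 0.55. The collagen receptor Gp6 was 46.4-fold higher as fitted, from a fresh level that was not well above background. Of the 18 members, 15 were already well above background in fresh cells and 3 also belong to another list. limma called 13 of the 18 adjusted over the list alone (smallest adjusted p = 0.00389).

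Cholesterol synthesis and uptake genes had a median of 2.15, above all random lists, with 19 of 25 at least 2-fold higher. The lanosterol synthase Lss was at least 14.0-fold higher. Farnesyl diphosphate synthase (Fdps) was higher by 4.74 ± 0.44 and mevalonate diphosphate decarboxylase (Mvd) by 4.73 ± 0.45. The sterol reductase Tm7sf2 was at least 9.42-fold higher on a probe at background in fresh cells, and higher by 0.79 on a second probe. The 1 member at least 2-fold lower on both arrays was Pcsk9, which promotes degradation of the LDL receptor. It was singled out after its values were seen and was at least 6.46-fold lower. limma called 17 of the 25 adjusted over the list alone (smallest adjusted p = 0.00932). Fatty acid synthesis and desaturation genes had a median of 0.89 at the 99.95th percentile, with 8 of 18 higher and 0 lower. The desaturases Scd1 and Fads2 were higher by 3.12 ± 0.49 and 2.41 ± 0.46 (6.39 on a second probe of Fads2), and the malic enzyme Me1 at least 11.3-fold higher (2.85 on its lowest probe). Fads3 was at least 8.63-fold higher on a probe at background in fresh cells, but at -1.18 on a second probe. limma called 3 of these 18 adjusted over the list alone (smallest adjusted p = 0.0284).

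**Figure D1:**
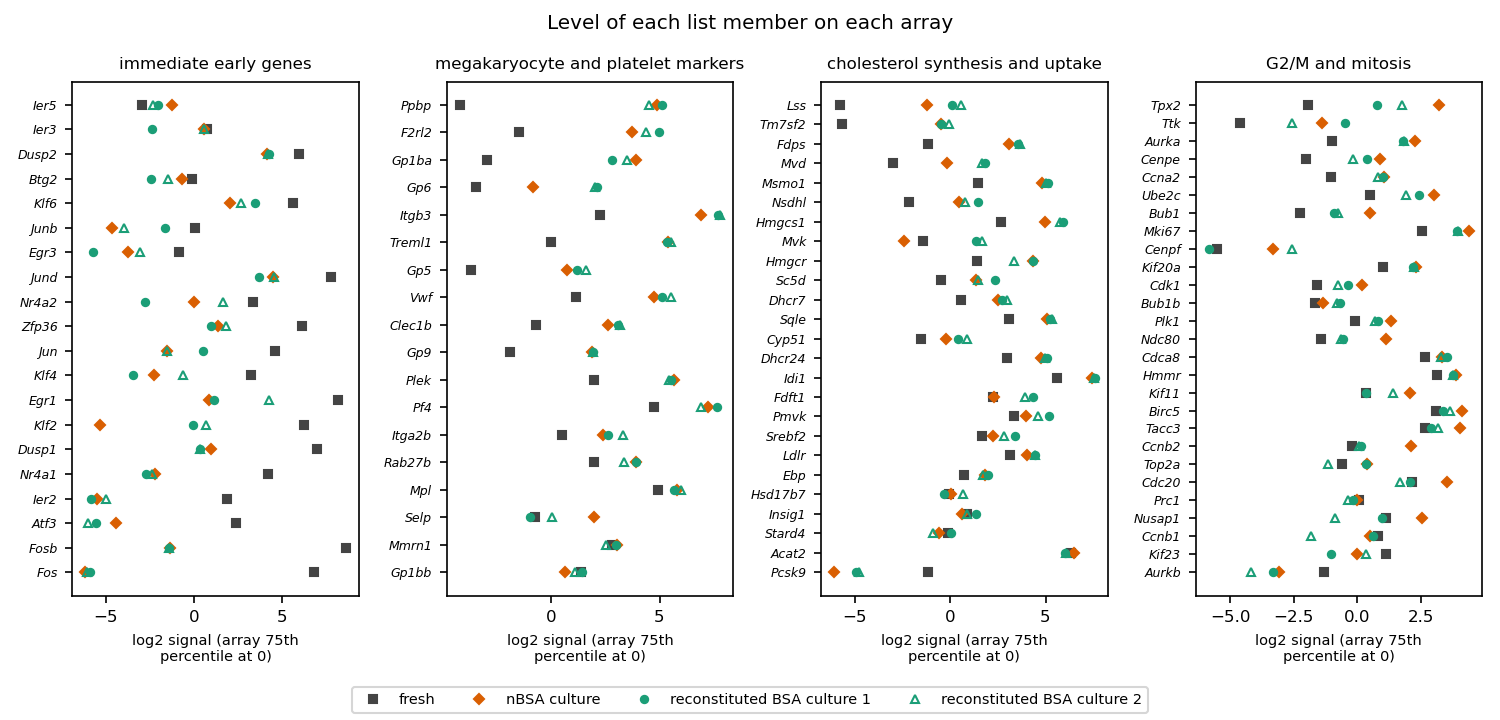
Levels of each measured member of 4 gene lists on each array, as log2 processed intensity with the array's 75th percentile at 0. Squares stand for the fresh array, diamonds for nBSA and circles and open triangles for both reconstituted BSA arrays, and genes are ordered by the difference between reconstituted BSA and fresh. Fos lay at 6.82 in fresh cells and between -6.16 and -5.89 in the 3 cultured arrays, while Ppbp lay at -4.18 in fresh cells and between 4.51 and 5.10 in culture.

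Hypoxia response genes had a median of 1.37, above all random lists, or 1.25 with genes near background at their bound, with 9 of 19 higher and 4 lower. The growth factor Vegfa was higher by 3.36 ± 0.44, though by 0.14 on a second probe. Hif3a, a regulator of the hypoxia-inducible factors, was higher by 3.75 ± 0.56 with a log2 difference of -1.66 on another probe. The prolyl hydroxylase P4ha1 was at least 1.68-fold higher, so a 2-fold difference is not assured for it. The MAX-binding repressor Mxi1 was at least 7.07-fold lower. Glycolysis genes had a median of 0.53 at the 99.94th percentile, with 6 of 19 higher and 1 lower. The aldolase Aldoc was higher by 2.14 ± 0.45, phosphoglycerate mutase Pgam1 by 1.75 ± 0.44 and the lactate exporter Slc16a3 at least 4.32-fold (3.88 on a second probe). Fatty acid oxidation genes had a median of 0.34 at the 97.8th percentile, with 7 of 22 higher and 0 lower. They included Cpt1a, which loads fatty acids for entry into mitochondria (1.86 ± 0.45, and 0.41 on a second probe), and the dehydrogenase Acadl (1.80 ± 0.44). This list had a median of -0.02 when the probes of a gene were averaged. Autophagy and lysosome genes had a median of 0.40 at the 98.5th percentile, with 2 of 20 higher, among them the lysosomal channel Mcoln1 (1.12 ± 0.45), and 1 lower, Gabarapl2 (-1.57 ± 0.44). limma called 0 genes of the hypoxia, glycolysis, fatty acid oxidation and autophagy lists adjusted over the list alone, with 9, 3, 5 and 1 genes at an unadjusted p under 0.05.

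Genes of G2/M and mitosis had a median of 0.82 at the 99.95th percentile, or 0.76 with genes near background at their bound, with 9 of 27 higher and 1 lower. The spindle assembly factor Tpx2 was higher by 3.20 ± 0.66 and by 0.82 on a second probe. The mitotic kinase Aurka was higher by 2.83 ± 0.44 and the checkpoint kinase Ttk at least 3.86-fold higher. Ttk lay at -0.50 and -2.57 on the reconstituted BSA arrays, and its bound rests on their mean. The 1 member at least 2-fold lower on both arrays was the kinase Aurkb, at -2.42 ± 0.62. Genes of DNA replication and S phase had a median of -0.45 and did not stand apart. limma called 0 of the 27 mitosis genes adjusted over the list alone, with 8 at an unadjusted p under 0.05.

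Interferon response genes had a median of -1.62, below all random lists, or -1.41 with genes near background at their bound, with 11 of 21 lower and 0 higher. Ifit3 was at least 19.2-fold lower, Ifit1 at least 5.87-fold lower and Mx1 at least 2.30-fold lower, all antiviral effectors, and Ifitm1 was at -4.54 ± 0.91. Cytokine and STAT5 targets had a median of -1.06 at the 0.07th percentile, with 7 of 18 lower and 2 higher. The feedback inhibitor Socs3 was at least 45.5-fold lower, Cish, another inhibitor of the same family, was at -5.58 ± 1.08, and the kinase Pim2 was at least 2.96-fold lower. Monocyte, macrophage and dendritic cell markers had a median of -0.97 at the 1.05th percentile, with 7 of 15 lower and 0 higher. Among them were the MHC class II invariant chain Cd74 (-6.69 ± 0.99), the endosomal protein Cd68 (-4.43 ± 0.65), the beta-glucan receptor Clec7a (-3.75 ± 0.60) and H2-Aa, which was at least 4.82-fold lower. Heat shock proteins had a median of -0.74 at the 2.31st percentile, with 5 of 12 lower and 1 higher. Hspb1 was at least 14.6-fold lower, Hspa1a at least 14.4-fold lower and Hsp90aa1 at -1.82 ± 0.45. Adjusted over the list alone, limma called 2 interferon, 8 cytokine, 6 monocyte and 2 heat shock genes (smallest adjusted p = 0.0117, 0.00625, 0.0216 and 0.00791).

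**Figure D2:**
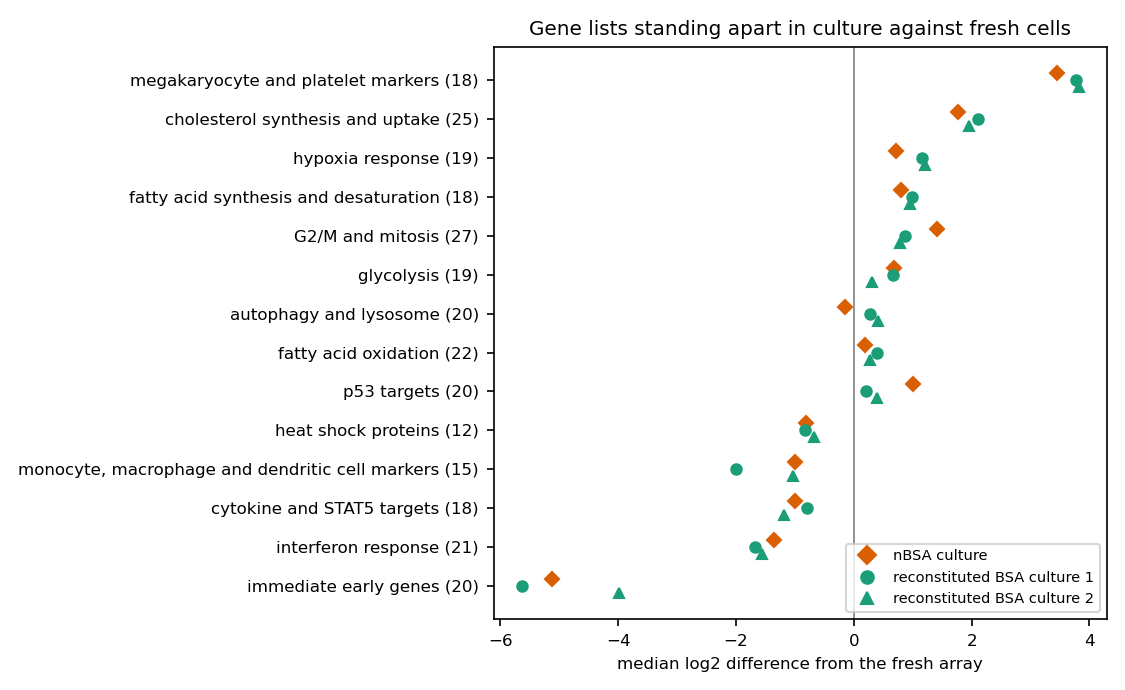
Median log2 difference from the fresh array of each gene list that stood apart in at least 1 of both cultures, with the number of measured genes in brackets. Diamonds stand for the nBSA array and circles and triangles for both reconstituted BSA arrays. Immediate early genes lay lowest (-5.64 and -3.98 on the reconstituted BSA arrays, -5.13 for nBSA). Megakaryocyte and platelet markers lay highest (3.77 and 3.82 on the reconstituted BSA arrays, 3.45 for nBSA).

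The sort markers differed in direction. Cd48, whose protein the gate excluded, was lower after culture (-4.24 ± 0.52), as were Ly6a, which encodes Sca-1 (-2.79 ± 0.45), and Procr, the endothelial protein C receptor (-2.39 ± 0.51). Itga2b, which encodes CD41, was higher by 2.45 ± 0.56. Flt3 was at least 4.30-fold higher on a probe at background in fresh cells, with -2.26 on another probe. Differences in Kit (0.45 ± 0.44), Cd34 (-0.03 ± 0.45) and the thrombopoietin receptor Mpl (0.88 ± 0.47) did not reach 2-fold on both arrays, and Slamf1, which encodes CD150, was not measurable. limma called 5 of these 8 genes adjusted over the list alone (smallest adjusted p = 0.0265), while the list as a whole, with a median of 0.21, did not stand apart.

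HSC identity genes had a median of -0.16 and did not stand apart, with 6 of 34 higher and 5 lower. The higher ones included Vwf (4.15 ± 0.49, and 2.10 on a second probe), Nupr1 (3.16 ± 0.46) and Hoxb5, which was at least 19.1-fold higher but lay at -0.87 and 2.42 on the reconstituted BSA arrays. Egr1, which the list shares with the immediate early genes, was at -5.47 ± 1.58. Quiescence genes had a median of -0.62 at the 2.63rd percentile and did not stand apart, with 7 of 23 lower and 2 higher. The lower ones included Klf2, a transcription factor of quiescent T cells (-5.98 ± 0.57), and Nr4a1 (-6.79 ± 0.46), both also immediate early genes. By its mean the quiescence list lay at the 0.2nd percentile. That mean weighs the large differences of Klf2, Nr4a1 and Egr1, which is in this list as well, so it is not separate from the immediate early list. Adjusted over the list alone, limma called 3 of the 23 quiescence genes (smallest adjusted p = 0.0128) and 0 of the HSC identity genes.

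Beside the megakaryocyte markers no lineage list stood apart as higher. Neutrophil and granulocyte progenitor markers had a median of -0.69 and did not stand apart, with 6 of 13 lower and 1 higher. The granule proteins Ngp and Ltf were well above background in fresh cells and not in culture, at least 28.8-fold and 6.08-fold lower. S100a9 lay at 2.69 in fresh cells and at -1.56 and -6.27 on the reconstituted BSA arrays. Medians were 0.19 for erythroid markers, 0.36 for mast cell, basophil and eosinophil markers, -0.21 for B cell markers, -0.36 for T and NK cell markers, -0.80 for stromal and endothelial markers and -0.41 for multipotent and lymphoid progenitor markers, none of which stood apart. With genes near background at their bound the medians were 0.01 for erythroid markers, -0.28 for B cell markers and 0 for mast cell markers. Thy1, a T cell and progenitor surface protein, was at least 35.2-fold lower. The remaining lists that did not stand apart were MYC and ribosome biogenesis (median -0.24), TCA cycle and respiratory chain (-0.48), PPAR targets and lipid storage (0.03), LXR targets and cholesterol efflux (0.08, or 0 with genes near background at their bound), ER stress and amino acid response (-0.27), p53 targets (0.31), antioxidant and NRF2 targets (-0.24), NF-kB and inflammatory response (-0.30) and adhesion and niche interaction (0.04). Among the LXR targets the lipoprotein Apoe was lower at -4.24 ± 0.44 and the exporter Abcg1 at -3.32 ± 0.50, while Mylip was at least 8.32-fold higher on a probe at background in fresh cells, with -3.77 on a second probe. The p53 and NF-kB lists held Fas, at least 13.1-fold lower, and Tnf, at least 14.6-fold lower. The median and the mean differed in sign for 5 lists (PPAR, LXR, adhesion, erythroid and sort markers), none of which stood apart. By the mean, 15 lists stood apart in place of 13 by the median. The neutrophil (0.02nd percentile), multipotent and lymphoid progenitor (0.33rd) and ER stress (1.85th) lists did so only by the mean, as did the quiescence list. The fatty acid oxidation and autophagy lists did so only by the median. Adjusted over the list alone, limma called 5 NF-kB, 4 LXR, 3 neutrophil, 2 erythroid and 2 multipotent and lymphoid progenitor genes (smallest adjusted p = 0.0105, 0.0130, 0.00661, 0.0286 and 0.0222). It called 1 gene each of the T and NK cell, p53 and ER stress lists (adjusted p = 0.00954, 0.0153 and 0.00723) and 0 genes of the other lists that did not stand apart here.

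Single genes spanned a similar range. The potassium channel gene Kcnj5 was at least 304-fold higher, with levels of 4.94 and 4.59 in culture, and its probe lies on chromosome 9 from 32122418 to 32122477 (mm9). The SNARE protein gene Stx11 was at least 116-fold higher, coagulation factor F10 at least 105-fold, the muscle genes Myom1 and Csrp3 at least 85.3- and 82.6-fold, Prr15 at least 60.4-fold and the neuropeptide gene Npy at least 57.1-fold. In the other direction the major urinary protein gene Mup19 was at least 52.3-fold lower, C1ql1 at least 36.8-fold and Arl11 at least 32.0-fold, lymphotoxin beta (Ltb) was at -7.60 ± 0.73 and the lectin gene Clec2f at least 27.6-fold lower. Cmah and Ltbp1 were at least 73.9-fold and 120-fold higher on probes at background in fresh cells, but higher by 2.42 and 0.63 on their second probes. On both reconstituted BSA arrays 2182 genes were at least 2-fold higher and 2386 at least 2-fold lower, 27.3% of those measured, where simulated unchanged genes gave 2155. limma called 0 of 16719 genes (smallest adjusted p = 0.154), with 2916 at an unadjusted p under 0.05 against 836 expected by chance, and eBayes with trend and robust also called 0, with 3262. Whether more genes were higher or lower depended on scaling, since 2540 were higher and 1905 lower with the 75th percentile over probes well above background on all arrays, and 749 and 1095 with normexp background correction. The fatty acid oxidation, heat shock, autophagy, cytokine and monocyte lists no longer stood apart under at least 1 alternative, and the 2-fold count was 1844 with normexp background correction and 2673 among genes well above background on all arrays.

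The nBSA culture was set against fresh cells for the same question, with 1 array each and so with no measure of error. The main groups had the same directions as in reconstituted BSA, and p53 targets also stood apart as higher. In all, 7 of the 33 lists stood apart as higher and 5 as lower. Immediate early genes had a median of -5.13, with 17 of 20 at least 2-fold lower and 1 higher. Fos was at least 1946-fold lower and Klf2 at least 1346-fold lower (probe on chromosome 8 from 74845137 to 74845196, mm9), Fosb was at -10.00 and Ier2 at least 63.4-fold lower. Megakaryocyte and platelet markers had a median of 3.45, with 15 of 18 higher and 0 lower. Ppbp was at least 333-fold higher, Gp1ba was at 6.83, the platelet activation receptor Treml1 at 5.36 and F2rl2 at 5.19. Cholesterol synthesis and uptake genes had a median of 1.77, with 15 of 25 higher and 1 lower. Tm7sf2 was at least 8.15-fold higher (1.04 on a second probe), Fdps at 4.20 and Lss at least 4.88-fold higher, while Pcsk9 was at least 7.59-fold lower.

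Genes of G2/M and mitosis had a median of 1.42 in nBSA against fresh, or 1.41 with genes near background at their bound, with 19 of 27 higher and 2 lower. Tpx2 was at 5.12 (1.88 on a second probe), Aurka at 3.29, the kinetochore motor Cenpe at 2.90 and Ttk at least 4.27-fold higher. p53 targets had a median of 1.00 at the 99.93rd percentile, or 0.97 with genes near background at their bound, with 10 of 20 higher and 4 lower. Phlda3, an inhibitor of AKT signalling, was at least 15.7-fold higher and the pro-apoptotic Pmaip1 at least 3.00-fold higher. The cell cycle inhibitor Cdkn1a was at least 14.1-fold higher on a probe at background in fresh cells, with -0.59 on another probe, and the kinase Plk2 was at -3.71. Medians were 0.81 for fatty acid synthesis and desaturation, with Me1 at least 25.6-fold higher (2.88 on its lowest probe) and Fads2 at 2.51, and 0.68 for glycolysis, with Slc16a3 at least 10.4-fold higher (5.20 on a second probe) and Pgam1 at 1.86. The hypoxia response list had a median of 0.72 at the 99.1st percentile, with Vegfa at 3.10 (0.08 on a second probe) and Mxi1 at least 8.30-fold lower.

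Interferon response genes had a median of -1.36 in nBSA against fresh, with 12 of 21 lower and 0 higher, among them Ifit3 (at least 22.5-fold lower), Irf9 (-4.26) and the GTPase gene Gbp2 (-4.10). Cytokine and STAT5 targets had a median of -1.002, with Cish at least 73.5-fold lower, the kinase Pim1 at least 28.0-fold lower and Socs3 at -3.98. Monocyte, macrophage and dendritic cell markers had a median of -0.995, with Cd74 at -6.04 and Cd68 at -5.47. Heat shock proteins had a median of -0.82, with Hspb1 at least 17.1-fold lower and Hspa1a at least 16.9-fold lower. Medians of the lists that did not stand apart lay between -0.55 (quiescence) and 1.00 (mast cell, basophil and eosinophil markers, 0.08 with genes near background at their bound). By its mean the quiescence list lay at the 0.03rd percentile, with 8 of 23 lower and 2 higher. That mean weighs the large fitted differences of Klf2 (-11.64), Egr1 (-7.30) and Nr4a1 (-6.47), all also immediate early genes. It is therefore not separate from the immediate early list. HSC identity lay at the 0.67th percentile by its mean and at the 37.3rd by its median, with 10 of 34 lower and 5 higher. Its mean weighs Egr1, Procr, Clec1a and Mecom, given next. Ly6a was at -5.54, Procr at -4.74 and Egr1 at -7.30. Within HSC identity, Clec1a was at least 39.0-fold lower and the transcription factor Mecom was at least 34.03-fold lower on a probe at background in nBSA, with 0.18 on another probe.

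Among single genes, Bsn was at least 371-fold higher in nBSA than in fresh cells, Kcnj5 at least 208-fold, the phospholipase Plcb1 at least 146-fold (but 4.68 on its lowest probe), Myom1 at least 112-fold, Stx11 at least 68.9-fold, F10 at least 68.2-fold and the adhesion receptor Cd226 at least 56.0-fold (5.77 on a second probe). Zrsr2 and Ltbp1 were at least 68.8-fold and 161-fold higher on probes at background in fresh cells, but at -5.11 and 1.17 on their lowest probes. The splicing factor gene Slu7 was at least 147-fold lower, S100a9 at least 111-fold, the protease Ctss at least 83.1-fold, Mup19 at least 61.4-fold, Lrtm2 at least 51.7-fold and the peptide gene Apln at least 46.1-fold, and the common gamma chain Il2rg was at -7.49. Some of these genes differed widely within the reconstituted BSA pair. Bsn lay at -5.81 and 0.98, Slu7 at -3.73 and 0.003, Lrtm2 at -5.75 and -0.60, Apln at -5.97 and -2.51 and S100a9 at -1.56 and -6.27. A single nBSA array cannot show whether its difference would recur. Counted over all genes, 3477 were at least 2-fold higher and 3392 lower, 41.1% of those measured, where simulated unchanged arrays gave 4886 and the pair of reconstituted BSA arrays differed this much in 4352 genes. The split was 3892 higher and 2938 lower with the 75th percentile over probes well above background on all arrays, and 1408 and 1668 with normexp. The cytokine, monocyte and hypoxia lists lost their place outside the random lists under at least 1 alternative, and the 2-fold count was 3076 with normexp background correction and 4157 among genes well above background on all arrays.

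Reconstituted BSA and nBSA cultures were compared to see how the albumin preparation bore on the cells at the same culture time. The name of the file deposited for the nBSA sample can be read as fatty acid added to BSA, so the lipid content of that medium is unsure and no difference in lipid genes can be tied to a defined albumin. Cholesterol synthesis and uptake genes had a higher median in reconstituted BSA, and genes of G2/M and mitosis and p53 targets a lower one. The medians of the ER stress and antioxidant lists were also lower. In each of these 5 lists most members were on neither side by the size rule. For cholesterol synthesis these were 20 of 25, for mitosis 21 of 27 and for p53 targets 15 of 20. Over all genes 14.98% passed that rule. Of 33 lists, 1 stood apart as higher and 4 as lower, where 3 stood apart between both reconstituted BSA arrays. Cholesterol synthesis and uptake genes had a median log2 difference of 0.49 at the 99.98th percentile, with 5 of 25 at least 2-fold higher on both arrays and 0 lower. Mevalonate kinase (Mvk) was higher by 3.91 ± 0.46, with -0.25 on a second probe, Mvd by 1.92 ± 0.45, squalene synthase (Fdft1) by 1.86 ± 0.48 (0.16 on a second probe) and Lss by 1.52 ± 0.50. Genes of G2/M and mitosis had a median of -0.77, below all random lists, with 6 of 27 lower and 0 higher. Cyclin B2 (Ccnb2) was at -1.99 ± 0.44, Nusap1, which bundles spindle microtubules, at -2.50 ± 1.00, Tpx2 at -1.92 ± 0.66 and the kinetochore protein Ndc80 at -1.74 ± 0.44.

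p53 targets had a median of -0.62 in reconstituted BSA against nBSA at the 0.52nd percentile. By fitted values 4 of 20 were lower and 1 higher, and the bound of Eda2r given next is under 2-fold. The death receptor Fas was at least 2.55-fold lower, Pmaip1 at least 3.93-fold and Eda2r at least 1.94-fold, while Cdkn1a lay at 0.33 in nBSA and at 0.03 and -4.24 in reconstituted BSA, with a difference of -0.01 on another probe. ER stress and amino acid response genes had a median of -0.37 at the 2.33rd percentile, with 4 of 20 lower by fitted values. Among them were the tryptophanyl-tRNA synthetase Wars (-3.15 ± 0.47, and -1.04 on a second probe) and Atf3. Atf3 lay at -4.40 in nBSA and at -5.58 and -6.01 in reconstituted BSA, all at background, so its difference is not known. The serine synthesis enzyme Psat1 was at -1.46 ± 1.04. Antioxidant and NRF2 targets had a median of -0.36 at the 1.44th percentile, with 2 of 19 lower, among them sulfiredoxin Srxn1 (-1.86 ± 0.52), and 1 higher. Thioredoxin reductase Txnrd1 was at -1.38 ± 0.63, short of 2-fold on 1 array. limma called 0 genes of these 5 lists adjusted over the list alone, the smallest adjusted p being 0.0507 for p53 targets and 0.0737 for cholesterol synthesis.

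**Figure D3:**
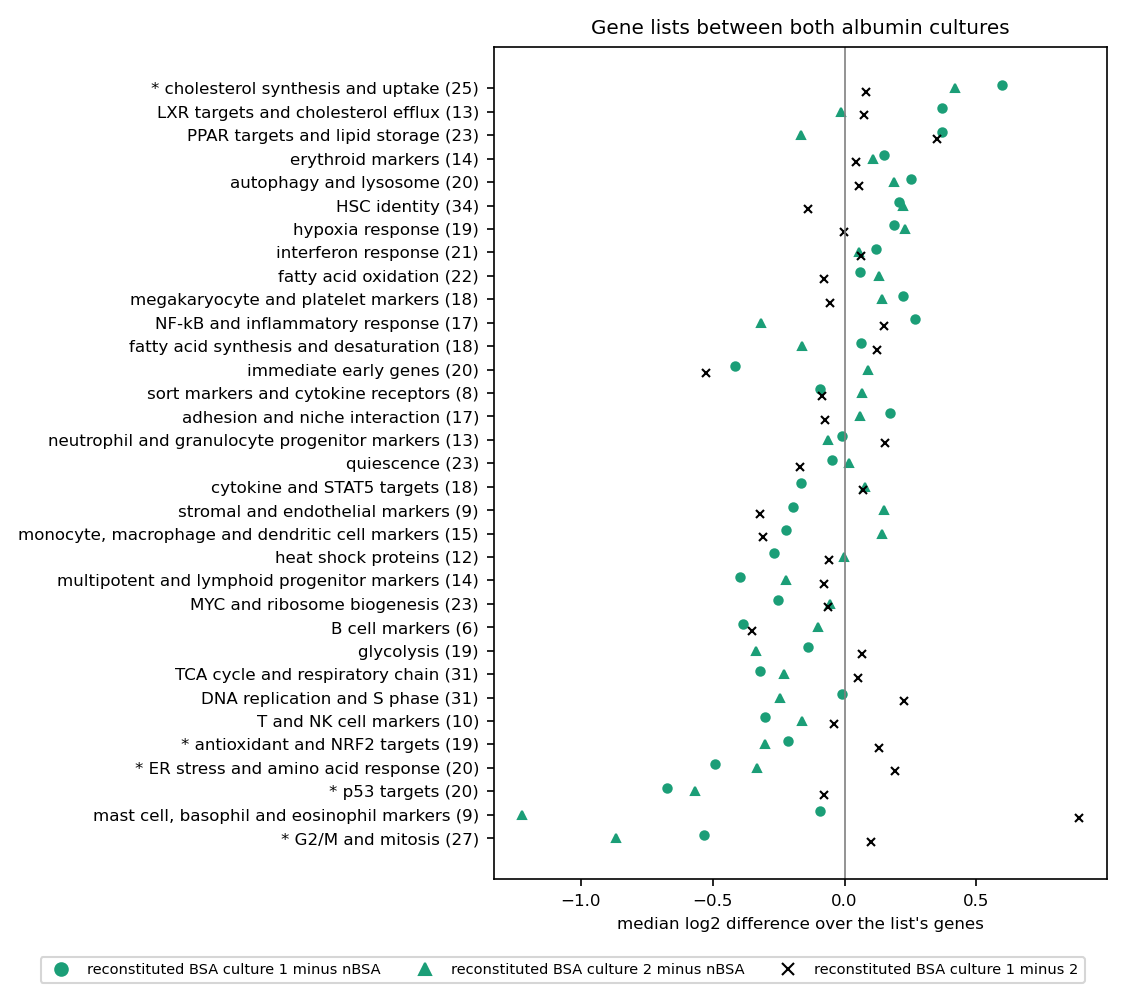
Median log2 difference of each of the 33 gene lists between each reconstituted BSA array and the nBSA array (circles and triangles) and between both reconstituted BSA arrays (crosses), with the number of measured genes in brackets and an asterisk at the 5 lists that stood apart. Cholesterol synthesis lay at 0.60 and 0.42 against nBSA and 0.08 between the pair, and G2/M and mitosis at -0.53 and -0.87 against nBSA and 0.10 between the pair.

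HSC identity genes had a median of 0.18 in reconstituted BSA against nBSA at the 97.0th percentile and did not stand apart. By fitted values 3 of 34 were at least 2-fold higher on both arrays, 1 was lower and 30 were neither. By their mean of 0.60 they stood apart, as 10 lists did by the mean in place of 5 by the median. That mean weighs a few large fitted differences, among them those of Mecom and Clec1a. Procr was higher by 2.35 ± 0.51, Clec1a at least 25.8-fold higher, Hoxb5 by 2.55 ± 1.67 and Mecom at least 10.6-fold higher on the same probe, with 0.23 on another. Mecom lay at -2.55 and 1.15 on the reconstituted BSA arrays, and its bound rests on their mean. Ly6a was higher by 2.75 ± 0.45. Medians of the other lists that did not stand apart lay between -0.67 (mast cell, basophil and eosinophil markers) and 0.36 (LXR targets and cholesterol efflux), and that of PPAR targets and lipid storage was 0.26. Within the PPAR list the thioesterase Acot1 was at least 14.9-fold higher, Pdk4, which inhibits pyruvate oxidation, was higher by 3.53 ± 0.46, Cpt1a by 2.35 ± 0.45 (5.72 on a second probe), and lipoprotein lipase (Lpl) at least 9.19-fold lower, though at -1.96 on a second probe. The desaturase Scd1 was higher by 1.82 ± 0.49 and Gp6 by 2.88 ± 0.44, and the granule enzyme myeloperoxidase (Mpo) was at least 9.28-fold lower (-5.63 on a second probe). Between both reconstituted BSA arrays 3 lists stood apart, PPAR targets (0.35), mast cell markers (0.89) and immediate early genes.

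Among single genes the DNA sensor Aim2 was at least 41.2-fold higher in reconstituted BSA than in nBSA (levels 1.27 and 1.26 against a nBSA array at background, probe on chromosome 1 from 175396036 to 175396095, mm9). The glucocorticoid-induced transcription factor Klf9 was also at least 41.2-fold higher, the calpain Capn3 at least 35.4-fold, Abi3 at least 34.4-fold, the small GTPase Arl4c at least 26.0-fold, Klf2 at least 21.3-fold, Ell3 at least 15.7-fold, Pip4p1 at least 14.4-fold and interleukin 6 (Il6) at least 12.6-fold. Zfp287 was at least 25.02-fold higher on a probe at background in nBSA, but at -1.23 on its lowest probe. In the other direction the metallothionein Mt2 was at least 109-fold lower (probe on chromosome 8 from 96697371 to 96697430, mm9), Klhl23 at least 23.9-fold, Snx21 at least 21.0-fold, Tnp2 at least 15.1-fold, Fam229b at least 14.3-fold and Prdm8 at least 8.25-fold, and the beta globin Hbb-bt was at -6.16 ± 0.70. On probes at background in reconstituted BSA, Zfp27 was at least 12.1-fold lower (0.96 on a probe taken only with no filter on dim probes), Lexm at least 16.8-fold lower and Wdsub1 at least 65.4-fold lower, but with 0.86 on a second probe of Wdsub1. Adjusted over the list alone, limma called Klf2 in both the immediate early and the quiescence list (adjusted p = 0.0368 and 0.0424), Il6 (0.0150) and Hbb-bt (0.0370). Over all 16719 genes limma called 0 (smallest adjusted p = 0.458), with 1394 at an unadjusted p under 0.05 against 836 expected by chance, and eBayes with trend and robust called 0, with 1383. At least 2-fold apart on both arrays were 1134 higher and 1370 lower genes, 14.98% of those measured, where simulated unchanged genes gave 2155. The ER stress list stood apart under 5 of 11 alternatives and lay at the 5.23rd percentile on 1 of both arrays alone, the antioxidant list stood apart on neither array alone, the p53 list did not among genes well above background on all arrays, and the 2-fold count was 624 with normexp background correction and 1233 among genes well above background on all arrays. Among the 5 for ER stress were the authors' table, removal of saturated genes and scaling on probes well above background, which could hardly move a list.

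The 3 cultured arrays lay at nearly the same distance from the fresh array. Over 12584 genes well above background on every array, the standard deviation of the log2 difference from fresh was 1.25 for nBSA and 1.25 for each reconstituted BSA array, with Pearson's r across genes of 0.879, 0.878 and 0.877. Between nBSA and the reconstituted BSA arrays the standard deviation was 0.958 and 0.916, and between both reconstituted BSA arrays 0.877, with r of 0.928, 0.933 and 0.939. Genes are not independent replicates, and these correlations describe the arrays only.

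The differences from fresh cells were correlated between both cultures. Across 16719 genes the log2 differences had r = 0.768. Simulated unchanged cultures measured against the same single fresh array gave a mean of 0.578 and at most 0.594. The covariance was 2.18 against a simulated 0.672. Both cultures had 1677 genes at least 2-fold higher and 1739 lower in common, such as Kcnj5 and Ppbp among the higher and Fos, Fosb and Mup19 among the lower, where the simulation gave 718 and 714. In 91 genes the cultures lay at least 2-fold apart from fresh in opposite directions, against 49.7 in the simulation. The noise of the single fresh array enters both sides of this relation and could not be split between them.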

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

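All tests named here, except limma between the cultures, were chosen after the results they bear on had been seen.

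In 91 genes the nBSA array and both reconstituted BSA arrays lay at least 2-fold from fresh cells on opposite sides, against 49.7 in simulated unchanged cultures, and 7 of them are named in the results. limma tested the differences between the cultures in these 7 and called none over all genes (adjusted p = 0.458 for each), and Hbb-bt only adjusted over its list alone (adjusted p = 0.0370). That they lay on opposite sides of the single fresh array was not tested. The metallothionein Mt2 (fitted log2 difference of -8.04 between reconstituted BSA and nBSA) and Snx21 (-6.354) were at background on both reconstituted BSA arrays, so only bounds hold, at least 109-fold and at least 21.0-fold lower. The beta globin Hbb-bt differed by -6.162, and all of these were higher in nBSA than in fresh cells. Wdsub1 (-6.964) and Zfp27 (-5.788) were also higher in nBSA than in fresh cells, though another probe of each differed between the cultures in the other direction. The probes used for Wdsub1 and Zfp27 were at background on both reconstituted BSA arrays, so only bounds hold, at least 65.4-fold and at least 12.1-fold lower, and Hbb-bt was at background on 1 of them. The mitochondrial kinase Pdk4 differed by 3.531 and was lower in nBSA than in fresh cells, and Pip4p1, fitted at 5.792, was at background in both fresh cells and nBSA, so it was at least 14.4-fold higher in reconstituted BSA than in nBSA and its side in nBSA against fresh cells is not known. Outside the named genes, 694 probes without a gene name were at least 4-fold above the fresh array on all 3 cultured arrays. That is 4.72% of the 14699 such probes well above background on any array, against 4.59% of probes with a gene name.

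The first pattern weighed is the low level of immediate early genes in all 3 cultured arrays. Scaling or background correction as the whole cause is excluded, because under 3 other scalings the list's median nearest to 0 on any cultured array was -3.10. Sorting and handling induce these genes, and stress of that kind in the fresh cells may have raised them there. Heat shock genes, which such stress also induces, were low in culture too, with a highest percentile of 5.01 over the cultured arrays, which leaves this explanation open. Whether 7 days of culture lowered these genes was not tested apart from handling, and the labels differ on whether cultured cells were sorted again.

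The second pattern is the high level of megakaryocyte and platelet genes in all 3 cultured arrays. Scaling as the whole cause is excluded, since the smallest median under 3 other scalings was 2.44. Maturation of cells toward several lineages stays open. Of 6 other lineage lists, 0 stood apart as higher in both cultures and 1 stood apart as lower, but their 67 members went both ways. By fitted values 14 were at least 2-fold higher and 18 lower in nBSA than in fresh cells, and 5 higher and 21 lower in reconstituted BSA. These counts may include genes at background in fresh cells, for which a 2-fold difference is not assured. Lower levels of transcripts already present in fresh cells do not show whether some cultured cells matured. Cells of the megakaryocyte lineage could account for the pattern. That 14 of 18 markers were at least 2-fold higher on all 3 cultured arrays restates the pattern and does not favour such cells. The probes brightest in culture were those of Itgb3 and Pf4. They lay at 2.26 and 4.77 in fresh cells and between 6.90 and 7.79 in culture, though intensity does not rank transcripts. A change within the stem cells cannot be told apart from such cells on bulk arrays. Of the 18 markers, 15 were well above background in the freshly gated CD41-negative cells. The labels also differ on whether cultured cells were sorted again, so whether CD41-positive ones were removed is not known.

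The third pattern is the higher cholesterol synthesis list and the lower mitosis list in reconstituted BSA than in nBSA. Scaling is excluded for both parts, with medians nearest to 0 of 0.286 and -0.449 under 3 other scalings, beyond the lists' differences between both reconstituted BSA arrays. Spread between arrays of 1 condition stays open, although the pair differed by only 0.0814 and 0.101 in these lists (57.6th and 72.4th percentile), since 1 pair cannot show how far a second nBSA array might lie. The albumin preparation as a biological explanation was not tested apart from that lone array.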

How the results depend on the processing

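All alternatives named here were set before the data were examined, except the scalings of the ribosomal protein and histone groups, chosen after they were noticed. limma called 0 genes in both comparisons with reconstituted BSA under each alternative. Simulated changes, set in few genes and only against fresh cells, were never called, so this 0 is not read as stability. The size rule used in its place gave 4568 (against fresh) and 2504 (against nBSA). For nBSA against fresh, limma with the spread of the reconstituted BSA pair called 0 genes (smallest adjusted p = 0.196) and a 4-fold threshold left 3183 of 6869. With normexp background correction the 2-fold counts were 1844, 624 and 3076 for reconstituted BSA against fresh, against nBSA, and nBSA against fresh. Among genes well above background on all arrays they were 2673, 1233 and 4157, where fewer genes were tested. The balance of higher and lower genes followed the scaling: 2182 to 2386 for reconstituted BSA against fresh became 2540 to 1905 with the 75th percentile over probes well above background on all arrays and 749 to 1095 with normexp. With 1 reconstituted BSA array left out, which relaxes the rule to 1 array, the total 2-fold counts were 6855 and 6874 against fresh and 4787 and 5061 against nBSA. The distance of the reconstituted BSA arrays from fresh relative to that of nBSA was 0.999, and 0.989 with normexp, 1.004 with quantile normalization, 0.995 with no filter and 0.992 with probes averaged. The relation between both cultures was r = 0.743 with no filter and 0.708 to 0.738 with 1 reconstituted BSA array left out. By the mean in place of the median, 10 lists stood apart between the cultures in place of 5. The fatty acid oxidation list reversed to -0.0225 with probes averaged, and Zfp27 between the cultures to 0.956 with no filter, where another probe stood for it. The causes were not tested. Other values kept their direction: 79 of the values for whole comparisons stayed close and 22 moved, 39 list values came to stand apart, 28 ceased to and 955 kept their side, and 1657 values of named genes kept their direction. Some alternatives could hardly change a list. The authors' table held the main values, removal of saturated genes removed none, and scaling on probes well above background shifts each array by a constant. Large differences of named genes could also hardly change direction. Scaling on probes well above background shifted the median of all genes by 0.21 (reconstituted BSA against fresh) and 0.16 (nBSA against fresh), and normexp shifted reconstituted BSA against nBSA by 0.11. Leaving out saturated genes removed none. No paired analysis was possible because the labels pair no arrays. Signal over background limits dim genes most, 39.4% of which lay 2-fold apart between both reconstituted BSA arrays in the lowest of 10 bins.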

Other observations

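The gene groups and all tests described here were chosen after the data were seen.

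Ribosomal protein genes, which encode the protein part of the ribosome, had medians below those of fresh cells in every culture at the main scaling. In reconstituted BSA against fresh cells, 83 of 83 had a negative log2 difference, with a median of -0.78 and quartiles of -0.996 and -0.54, below all random lists matched on level. In nBSA against fresh cells the median was -0.41, with 76 of 83 below 0, and between reconstituted BSA and nBSA it was -0.37, with 73 of 83 below 0. Both reconstituted BSA arrays differed from each other by a median of 0.14, at the 46.3rd percentile. Most of these are bright probes, so compression or scaling of bright signals may contribute. A few were dim, such as Rpl10l at -3.03 and Rpl7l1 at -2.19 in fresh cells. Under 3 other scalings the median nearest to 0 was -0.361 for reconstituted BSA against fresh, with an upper quartile of -0.13 and 70 of 83 genes lower, which excludes scaling as the whole of that difference. For nBSA against fresh it was -0.0973, with an upper quartile of 0.13 and 50 of 83 lower, so whether the group was lower there in itself stays open. Compression is excluded as the whole cause for both. Against the 50 genes nearest in level, the median nearest to 0 under any scaling was -0.595 for reconstituted BSA and -0.230 for nBSA, with upper quartiles of at most -0.332 and -0.0192, and nBSA against fresh lay at most at the 0.01st percentile of random lists matched on level. The hypothesis that culture lowered the transcripts of the ribosome was not tested in any other way.

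Core and linker histone genes, which package DNA, were also lower in culture. Over 40 genes the median was -1.07 in reconstituted BSA and -0.58 in nBSA against fresh cells, with 36 of 40 lower in each, and under quantile normalization the medians were -0.73 and -0.47. The pair of reconstituted BSA arrays itself differed by 0.45 in this group, above all random lists, and the median difference of reconstituted BSA from nBSA was -0.39 at the 0.22nd percentile, with 33 of 40 lower. On the single arrays it was -0.13, at the 18.6th percentile, and -0.58. Many histone genes have near-identical sequences, and probes of one were not tested for signal from another. Some nearly coincided on every array, such as H2ac15 and H2ac19 (6.28 and 6.24 in fresh cells, 5.44 each in nBSA). The 40 genes may therefore hold fewer independent signals, while the counts and the random lists treat each as its own.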
